A study of Mus musculus with 4 samples.

How the data were processed

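Total RNA from sorted mouse bone marrow cells was hybridised to Illumina bead arrays, with 1 array per sample. Per the labels, mice of the C57BL6/J strain aged 12 to 16 weeks were given pIpC, a double-stranded RNA mimic that switches on the interferon-driven Mx-Cre recombinase, 1 week before the marrow was harvested. Each sample came from its own pool of 3 to 5 mice, per the series' design text. The genotype and replicate number of every sample were taken from its title, which gave control replicates 1 and 2 and knockout replicates 1 and 3. RNA was isolated, cleaned up with DNase treatment, checked for quality and amplified to biotinylated cRNA, per the labels' protocols. The array type and the scanning and summarising software were not given in the sources used here.

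The deposited gene table held intensity values without background subtraction or normalization between arrays, per the file headers and the values themselves. The deposited intensity of a gene was a single number per gene name. How the probes of a name were combined was not given, and the place of any probe within its transcript was not known. The same deposited table gave a detection p-value against the negative control beads of each array, a bead standard error as a signal in intensity units, and the mean number of beads. The method behind the detection p-value was not given in the sources used here, and some bright genes with several probes had a detection p-value above the limit used. It held 30854 gene rows and 936 negative control probes, and 1 further gene row had been replaced by annotation text and was left out. The deposited value table held 30840 rows of linear intensity, each under a probe identifier. The 3954 of its rows above 300 all matched a row of the gene table after quantile normalization on the linear scale, within a tolerance of 1%, when columns were paired by label, against at most 224 under any other pairing. The matched values were therefore the intensities of the gene table, quantile-normalized without background subtraction, the scale was linear and no centring or ratio was involved. The column medians were 94.1 and 94.2 in the controls and 94.2 and 94.2 in the knockouts. No table used here pairs its identifiers with genes, so it served only for counts.

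Gene names were updated through a RefSeq gene table of the assembly GRCm38.p6, which was used for names alone. Of the names, 16223 matched a current symbol, 5684 an older symbol and 868 a gene identifier, and 8079 did not match and were kept as written, which left 28711 distinct genes or names. Of the 538 genes in the fixed lists, 523 had a row.

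Signals were background-corrected by the normexp method with the negative control probes, given an offset of 16, quantile-normalized between arrays and taken to log2 by the neqc function of limma 3.58.1 in R 4.3.3. Genes with a detection p-value under 0.05 on at least 2 of the 4 arrays were kept, and where rows shared a gene the row with the highest mean was used, which left 11538 genes. Knockout minus control was tested with limma's lmFit and eBayes functions, with no covariate, and adjusted by the Benjamini-Hochberg method over these genes with a threshold of 0.05. All tests were two-sided and every adjusted p given for a gene comes from this limma fit unless another setting is named. With 2 pools of mice per genotype, a gene's p-value and standard error combine the spread between these pools with a variance shared over all genes. That shared variance entered with 3.72 prior degrees of freedom. Camera p-values compare the genes of a list with other genes and mainly measure spread over genes. Errors on log2 changes are standard errors of that fit with 2 arrays per genotype. A gene is called above background on an array where its detection p is under 0.05. For a gene not above background on either array of a genotype, a bound on its change was also computed. The bound sets the mean of the brighter genotype against, per array of the dimmer one, the higher of the gene's own value and the lowest value of any gene above background. Where the gene's own values lie above that lowest value, the bound equals the fitted change.

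Gene lists were tested with limma's camera function, which compares a list with all other genes, at a preset correlation between genes of 0.01, adjusted over the 22 lists with at least 5 measured members. The same lists were tested with an estimated correlation and with limma's fry function, whose p-value asks whether a list's genes move, on balance, in a single direction. Similarity of arrays was described by Pearson correlation across genes and by principal components. The genes named were fixed by rule: Mybl2, then the 12 genes per direction with the largest log2 change among those past the adjusted threshold without overlap of the genotypes, filled where there were too few from genes with an unadjusted p under 0.01 and no overlap. For each list the rule took the members past the adjusted threshold or, where there were none, the 2 members with the largest log2 change; 1 gene that this rule takes is not reported here. List members named beyond that rule were chosen after their values were seen, mostly because they passed the threshold adjusted over the list alone. The comparison, the lists, the naming rule and the alternative settings were set before the data were examined.

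The pipeline was tested on simulated data made for the comparison of knockout with control, with 11538 genes in 20 runs. In each run 200 genes were changed and, besides these, the granulocyte-monocyte progenitor list was shifted by a log2 of 1. It recovered 2.40% of genes changed by a log2 of 1, 76.0% of those changed by 2 and 93.7% of those changed by 3, and 5.50% of its calls were genes left unchanged. Among unchanged genes 5.03% had an unadjusted p under 0.05. The shifted list was called in 100% of runs and 0.200% of unshifted lists were called. Noise was drawn from the variance model of the fit itself, so the 5.03% was close to given. Each simulated gene varied independently of the others and no simulated array was dimmer. These rates therefore do not give the error of gene calls in the real data, or of list calls where genes are correlated.

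The alternatives tried were quantile normalization without background correction of signals floored at 16, cyclic loess or median scaling in place of quantile normalization, the deposited value table, no detection filter, detection p under 0.01 on all 4 arrays, eBayes with trend and robust settings, the mean of a gene's rows, other thresholds, the other list tests, and leaving out each array in turn. A fit without an array leaves a genotype with a single sample, which is then assumed to vary like the other genotype. Tables and plots were prepared with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The number of arrays limits the precision of every value.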

Results

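Gene expression was measured on 4 arrays in LSK cells, the lineage-negative, Sca-1-positive and Kit-positive fraction of mouse bone marrow that holds hematopoietic stem cells and early progenitors. 2 arrays came from control mice and 2 from mice in which B-myb, the gene of a cell cycle transcription factor now named Mybl2, was flanked by recombination sites and deleted through Mx-Cre. The comparison addressed what loss of B-Myb does to transcripts of stem and early progenitor cells. Signal differed between arrays. The median signal was 91.2 and 84.2 on control replicates 1 and 2 and 97.4 and 103.8 on knockout replicates 1 and 3, against 86.7, 80.7, 94.4 and 99.9 for the negative control probes of the same arrays. The genes with a detection p under 0.05 numbered 12297 and 13439 on the control arrays and 10761 and 8797 on the knockout arrays. Median log2 signal after background correction was 6.80 and 6.45 in the controls and 5.93 and 5.64 in the knockouts, so the knockout arrays were the dimmer ones before quantile normalization. Across 11538 genes, Pearson's r was 0.967 between the control arrays, 0.971 between the knockout arrays and 0.946 to 0.970 between genotypes, where genes are not independent replicates. The first principal component held 53.3% of the variance and placed the controls at −12.4 and −37.5 and the knockouts at 20.1 and 29.8. The second held 28.6% and divided the arrays across genotypes, with control replicate 1 at 20.5 and knockout replicate 1 at 18.3 against control replicate 2 at −15.4 and knockout replicate 3 at −23.3. Control replicate 1 correlated with knockout replicate 1 at 0.970 and with control replicate 2 at 0.967.

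Mybl2 itself was at a log2 intensity of 7.19 and 6.52 in the controls and 6.72 and 6.62 in the knockouts. The change was −0.18 ± 0.28 (SE), with a 95% confidence interval from −0.87 to 0.51, and did not pass the test (adjusted p = 0.776). It was 0.15 without control replicate 1 and −0.52 without control replicate 2. The detection p of Mybl2 was under 0.05 on both control arrays and on 1 of the 2 knockout arrays. On knockout replicate 3 that p was 0.112, although the signal of 146.5 exceeded the 95th percentile of that array's negative control probes (112.8). Because the deposited value is a single number from probes whose place in the gene is not known, it does not check the deletion, and the genotypes rest on the labels. Of the genes behind the sorting gate, Kit, the stem cell factor receptor, averaged 9.88 in the controls and 9.02 in the knockouts (change −0.86 ± 0.21, adjusted p = 0.237). Ly6a, which encodes Sca-1, differed by −0.20 ± 0.34, within the spread between arrays. Cd34, which is not part of the gate as given here, differed by −0.05 ± 0.24, also within that spread.

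Knockout LSK cells carried lower levels of megakaryocyte and stem cell genes and higher levels of granulocyte-monocyte progenitor genes than control cells, as groups. These calls came from camera with a preset correlation and were lost with an estimated correlation between genes (adjusted p = 0.589 with an estimated correlation for all 3 lists). The median change was −1.17 on the log2 scale for 15 megakaryocyte genes, −0.65 for 21 stem cell genes and 0.89 for 16 granulocyte-monocyte progenitor genes, and without background correction −0.67, −0.43 and 0.79. Mature neutrophil genes were not called as a list (camera, adjusted p = 0.0782). They were higher beside granulocyte-monocyte progenitor genes on knockout replicate 1 (median 2.44 relative to the control mean) and not on knockout replicate 3 (−1.01). Genes of DNA replication also ranked higher, with a median of 0.47 over 30 genes (−0.31 under median scaling, where all genes were at −0.70; adjusted p = 0.752 with an estimated correlation), while genes of mitosis did not move in a single direction. No single gene passed the test over all genes.

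Over all genes, 0 of 11538 passed an adjusted p of 0.05 in limma, and the lowest adjusted p was 0.114, shared by 20 genes. At an unadjusted p under 0.05 there were 1769 genes, 757 higher and 1012 lower in the knockout. That count was 933 without control replicate 2 and 1040 without knockout replicate 3. With the stricter detection filter the unadjusted split turned to 616 higher and 509 lower. With the main filter 1356 genes were not above background on either knockout array, 1231 of them lower, against 79 on the control arrays. Both knockout values lay on the same side of both control values for 5776 genes (50.1%). The average share over the 3 splits of the arrays is 33.3%, which genes that move together can exceed without an effect of genotype. Of the 5776 genes, 418 differed at least 2-fold, 150 higher and 268 lower. That 2-fold split was 116 higher and 117 lower with the stricter filter and 28 and 55 without background correction. It was 142 and 205 with cyclic loess and 13 and 3111 with median scaling. Other settings gave 3 genes past the adjusted threshold with cyclic loess, 14 with the stricter detection filter, 15 with trend and robust eBayes and 940 with median scaling, and 0 with the remaining normalization and filter settings and with each array left out. Median scaling aligned the arrays on the median of all 30854 rows before the detection filter. It therefore left the lower brightness of the knockout arrays in the tested genes, which are the genes meant by all genes. Their median change was −0.70 and the unadjusted split was 20 higher and 4368 lower, so directions there are read relative to that shift.

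The 24 genes named by rule, 12 higher and 12 lower, are given as values because none passed the test over all genes. They had the largest differences among genes with an unadjusted p under 0.01 and no overlap of the genotypes. Ms4a3, a marker of granulocyte-monocyte progenitors, differed by 2.76 ± 0.42, Trem3, a myeloid receptor, by 2.93 ± 0.24, Hp, which encodes haptoglobin, by 2.50 ± 0.24, and the Fc receptor gene Fcgr4 by 1.90 ± 0.39. Lrg1 (2.31 ± 0.48), Anxa3 (1.99 ± 0.34), the C-type lectin gene Mgl2 (2.00 ± 0.33) and Tgfbi (1.87 ± 0.22) were also among them. Dmkn, best known from skin, differed by 2.84 ± 0.26, and the mitochondrially encoded MT-ND5 by 2.33 ± 0.46. MRGPRA2 (2.96 ± 0.25) and MRGPRA7 (2.16 ± 0.24) belong to a family of close paralogs and are uncertain, since a probe may not tell the copies apart. The lower genes included Pf4, the platelet chemokine, at −2.81 ± 0.28, Car1, an erythroid carbonic anhydrase, at −2.36 ± 0.25, and Prss34, a basophil and mast cell protease, at −2.47 ± 0.44. An immunoglobulin kappa variable gene was at −2.95 ± 0.70 and is uncertain for the same reason as the MRGPRA genes, with controls at 8.24 and 10.52. Dusp1 (−2.34 ± 0.50) and Ppp1r15a (−2.15 ± 0.35), which respond to stress and growth signals, the chemokine gene Ccl3 (−2.48 ± 0.46) and the signalling regulator Rgs1 (−2.18 ± 0.26) were lower too. The list ended with Serinc3 (−2.57 ± 0.29), the long non-coding RNA Neat1 (−2.30 ± 0.49), Sult1a1 (−2.28 ± 0.50) and the unmatched name A430006M23RIK (−2.14 ± 0.29). The size of many of these differences depended on the normalization. Without background correction Dmkn was at 1.36, MT-ND5 at 1.25, Lrg1 at 1.00, MRGPRA7 at 0.90, MRGPRA2 at 1.78, Fcgr4 at 0.87 and Mgl2 at 0.98, and Ccl3 was at −1.46, Prss34 at −1.27, Neat1 at −1.26 and Sult1a1 at −1.11. Under median scaling, where all genes were at −0.70, Hp was at 1.60, Anxa3 at 1.21 and Tgfbi at 0.95. The immunoglobulin gene was at −1.81 without control replicate 2 and −4.09 without control replicate 1.

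**Figure D1:**
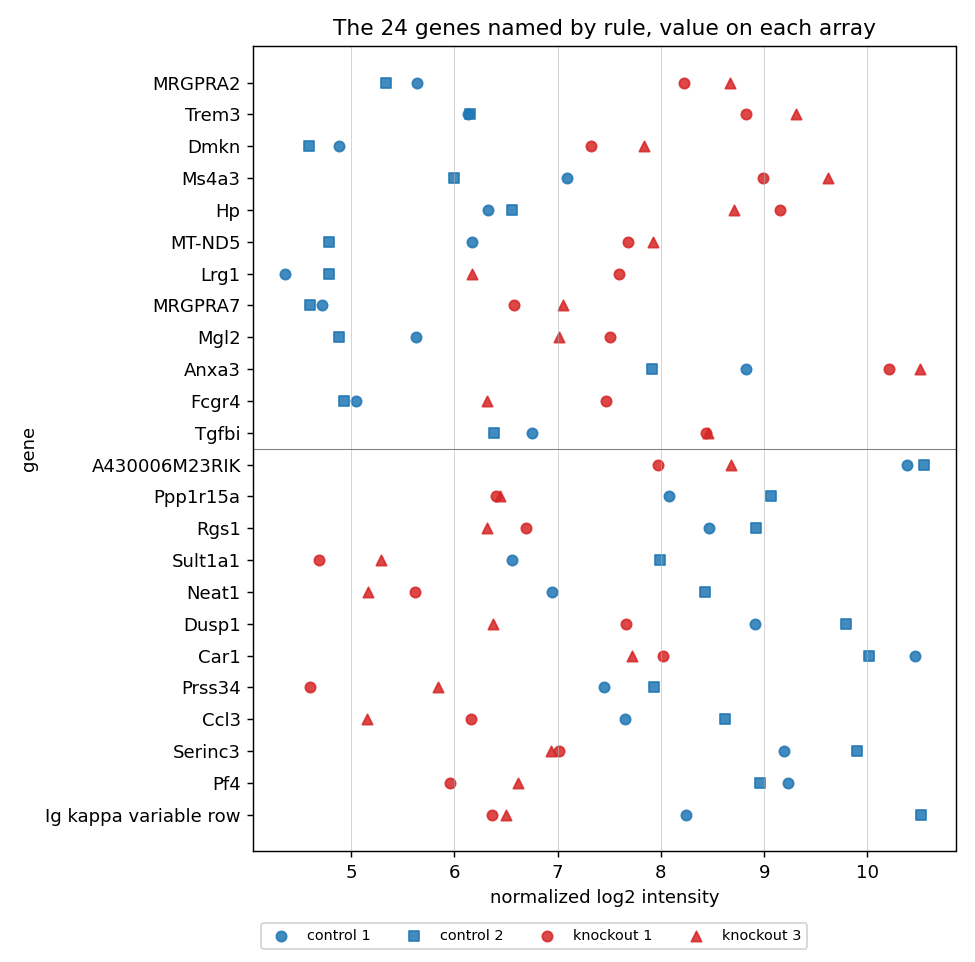
Normalized log2 intensity (horizontal axis) of the 24 genes named by rule, with 1 point per array and the genes higher in the knockout above the line. Both knockout arrays lie on the same side of both control arrays for every gene, for example Pf4 at 5.95 and 6.61 in the knockouts against 9.23 and 8.96 in the controls, and none passed the test over all genes.

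Megakaryocyte and platelet genes were the list with the lowest adjusted p (camera, adjusted p = 5.76e-08; adjusted p = 0.589 with an estimated correlation; fry, adjusted p = 0.181). 14 of its 15 measured members were lower, 13 passed the threshold adjusted over the list alone, all of them lower, and 0 passed over all genes. Pf4 differed most (−2.81 ± 0.28). Among the other members that passed over the list alone were Vwf, which encodes von Willebrand factor (−1.28 ± 0.20), and the platelet glycoprotein genes Gp5 (−1.54 ± 0.41) and Gp9 (−1.24 ± 0.27). Selp, which encodes P-selectin, was the exception at 1.52. Ppbp and Tubb1 were not above background in the knockout, and with both at their bounds the median of the list was −1.11. The list's median was −0.81 on knockout replicate 1 and −1.21 on knockout replicate 3 relative to the control mean, with the controls within 0.02 of it.

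Markers of long-term stem cells ranked lower as well (camera, adjusted p = 5.08e-06; adjusted p = 0.589 with an estimated correlation; fry, adjusted p = 0.219). Of 21 measured members 17 were lower, 8 passed the threshold adjusted over the list alone, all lower, and 0 passed over all genes. The largest differences were in Sult1a1 (−2.28 ± 0.50) and the growth suppressor gene Ndn (−1.94 ± 0.22). Meis1 (−1.32 ± 0.34), Gata2 (−1.18 ± 0.30) and Gfi1b (−1.15 ± 0.26), transcription factors of stem and megakaryocytic cells, and Txnip (−1.35 ± 0.22) passed over the list alone. The list's median was −0.92 on knockout replicate 1 and −0.50 on knockout replicate 3. Ly6a, a member of the list and a gate gene, differed by less than the spread between arrays.

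Granulocyte-monocyte progenitor genes ranked higher (camera, adjusted p = 7.10e-08; adjusted p = 0.589 with an estimated correlation; fry, adjusted p = 0.181). 13 of 16 measured members were higher, 8 passed the threshold adjusted over the list alone, all higher, and 0 passed over all genes. Ms4a3 (2.76 ± 0.42) and Hp (2.50 ± 0.24) differed most, followed by the Fc receptor gene Fcgr3 (1.65 ± 0.37). The granulocytic transcription factor genes Cebpe (1.61 ± 0.24) and Gfi1 (1.07 ± 0.26) and the granule protease gene Ctsg (1.39 ± 0.31) passed over the list alone, while Mpo, the gene of myeloperoxidase, at 0.70 ± 0.27, and the granule protease gene Prtn3, at 0.85 ± 0.31, did not. Relative to the control mean the list's median was 0.76 on knockout replicate 1 and 1.08 on knockout replicate 3, and under median scaling the change was 0.24 where all genes were at −0.70. The mature neutrophil list moved with this list on a single array. Its median was 2.44 on knockout replicate 1 and −1.01 on knockout replicate 3, with the controls at −0.63 and 0.63, and it was not called (median change 0.57, adjusted p = 0.0782; 1 of 16 members, Anxa1, passed over the list alone and 0 over all genes). S100a8, a granulocyte calcium-binding protein gene, was at 12.55 on knockout replicate 1, 8.69 on knockout replicate 3 and 9.59 and 10.93 in the controls. Without knockout replicate 3 the neutrophil list was called higher (adjusted p = 5.69e-15), without knockout replicate 1 it was called lower (adjusted p = 0.00464), and without control replicate 2 it was called higher (adjusted p = 0.0192). With all arrays it was called higher with cyclic loess (median 0.90, adjusted p = 0.0239) and with median scaling (median 0.02 where all genes were at −0.70, adjusted p = 8.09e-09). Its members with the largest differences were Lcn2 (1.61 ± 0.99) and Chil1 (1.13 ± 1.00), both within the spread between arrays.

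**Figure D2:**
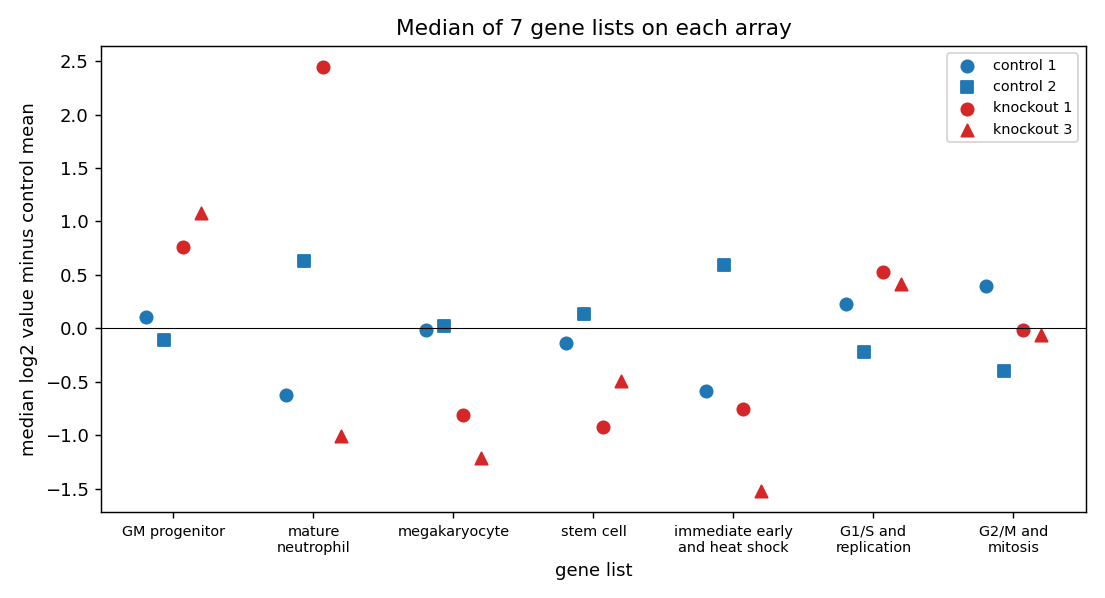
Median log2 value of 7 gene lists on each array, minus the mean of the control arrays, with 1 point per array. Granulocyte-monocyte progenitor genes lie at 0.76 and 1.08 on the knockout arrays, while mature neutrophil genes lie at 2.44 on knockout replicate 1 and −1.01 on knockout replicate 3.

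Genes of the G1/S transition and DNA replication ranked higher, and those of G2 and mitosis did not. In the replication list 26 of 30 measured members were higher (camera, adjusted p = 1.11e-05; adjusted p = 0.752 with an estimated correlation), and 0 passed the threshold adjusted over the list alone or over all genes. Gins1, a subunit of the replicative helicase (1.75 ± 0.46), and Rrm2, a subunit of ribonucleotide reductase (1.05 ± 0.34), differed most. Gins1 was at 8.59 and 7.20 in the controls and 9.72 and 9.57 in the knockouts. Rrm2 was at 6.66 and 5.78 in the controls and 7.45 and 7.08 in the knockouts, so control replicate 2 was the lower one in both genes. The median change of 0.47 was 0.31 without background correction and 0.20 without control replicate 2, and under median scaling it turned to −0.31, which was 0.39 above the median of all genes. The mitosis list, which holds targets of the complexes B-Myb joins, had 14 members higher and 12 lower (camera, adjusted p = 0.920), a median of 0.02, a mean of −0.03 and 0 of 26 members passing either way of adjusting. Nusap1, with no detection p under 0.05 in the knockout, was at −0.95 ± 0.37 and Prc1, a spindle protein gene, was at −0.92 ± 0.36. Mitotic genes separated the control arrays, with the list's median at 0.40 on control replicate 1 and −0.40 on control replicate 2, and the list was called higher without control replicate 1 (median 0.32, adjusted p = 0.0364) and lower without control replicate 2 (median −0.31, adjusted p = 0.0140). For the 12 measured genes of the Myb family and its DREAM and MuvB partners the median was 0.14 (adjusted p = 0.513), with 0 passing over the list alone or over all genes. That median was 0.28 without control replicate 1, 0.00 without control replicate 2 and 0.02 without knockout replicate 1. Tfdp1 was at 0.62 ± 0.27 and E2f5, with no detection p under 0.05 in the knockout, was at −0.80 ± 0.33.

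Genes of DNA damage repair and p53 targets were called higher relative to other genes by small amounts that depended on single arrays. The repair list had a median of 0.26 (0.21 with Rad50, which had no detection p under 0.05 in the knockout, counted as unchanged) over 19 members. Of these 15 were higher (camera, adjusted p = 0.0214, and adjusted p = 0.752 with an estimated correlation), with 0 passing over the list alone or over all genes. Its median was 0.16 without background correction and −0.60 under median scaling, 0.11 above that of all genes, and its call was lost without control replicate 2 (median 0.12, adjusted p = 0.251) and without knockout replicate 1 (adjusted p = 0.199), while without control replicate 1 the median was 0.42. H2ax, which encodes a histone variant that marks DNA breaks, was at −0.98 ± 0.21, against the direction of the list, and Fancd2 at 0.86 ± 0.32. The 19 p53 targets had a median of 0.06 and a mean of 0.23 (camera, adjusted p = 0.0415; adjusted p = 0.752 with an estimated correlation), and the median was 0.15 with cyclic loess, 0.23 with the stricter detection filter, where the call was lost (adjusted p = 0.0566), and −0.45 under median scaling, 0.25 above that of all genes. Phlda3 (1.22 ± 0.21) and Bax, a pro-apoptotic gene (1.09 ± 0.23), passed the threshold adjusted over the list alone, and 0 passed over all genes. This call was lost without control replicate 2 (adjusted p = 0.152) and without knockout replicate 1 (adjusted p = 0.382), and the median was 0.23 without knockout replicate 3 and 0.18 without control replicate 1. The 16 apoptosis regulators were not called (adjusted p = 0.513), with a median of −0.03 (0.07 without knockout replicate 3, −0.06 without control replicate 2 and 0.27 with the stricter detection filter), a mean of 0.10 and 0 passing over the list alone or over all genes. Bok was at 1.24 ± 0.30 and Mcl1 at −0.49 ± 0.20.

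Immediate early genes, which respond within minutes to stimulation and to handling of cells, ranked lower, and control replicate 2 stood apart in them. The list also holds inducible chaperone genes, of which Hsph1 was at 0.83 ± 0.40 and Dnajb1 at −0.40 ± 0.21. Hsph1 was at 9.60 and 8.58 in the controls, so control replicate 2 was the lower one there. The list had a median change of −0.74 over 17 members, 14 of them lower (camera, adjusted p = 0.00712, and adjusted p = 0.752 with an estimated correlation). 5 members, all lower, passed the threshold adjusted over the list alone and 0 over all genes. Fos, a subunit of the transcription factor AP-1, was at 8.19 and 10.63 in the controls and 7.15 and 5.49 in the knockouts (−3.09 ± 0.89). Egr1 was at 8.62 and 11.49 in the controls and 7.59 and 7.05 in the knockouts (−2.73 ± 0.89). The list's median was −0.59 on control replicate 1, 0.59 on control replicate 2, −0.76 on knockout replicate 1 and −1.52 on knockout replicate 3. Without control replicate 2 the call was lost (median −0.32, adjusted p = 0.251), and the median was −1.88 without control replicate 1 and −1.52 without knockout replicate 1. Without a detection filter it was −0.40.

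Interferon-stimulated genes and B lineage genes were called lower, and glycolysis and oxidative phosphorylation genes higher relative to other genes, each with a call that some array decided. 19 of 22 interferon-stimulated genes, a response that pIpC itself evokes, were lower (median −0.29, camera, adjusted p = 0.0206; adjusted p = 0.589 with an estimated correlation), with Isg20 at −1.03 ± 0.21 and Mx2 at −0.84 ± 0.23. The median was −0.17 without background correction and −0.18 without a detection filter. That call was lost without control replicate 2 (adjusted p = 0.160) and without knockout replicate 1 (adjusted p = 0.109). 10 of 11 B lineage genes were lower (median −0.50, camera, adjusted p = 0.0260; adjusted p = 0.752 with an estimated correlation), with Vpreb1, part of the pre-B cell receptor, at −1.54 ± 0.66 and Pou2af1 at −1.49 ± 0.42. The median was −0.16 without background correction and −0.31 with cyclic loess. The call was lost without control replicate 1 (median −0.27, adjusted p = 0.227) and without knockout replicate 3 (median −0.18, adjusted p = 0.170), and the median was −0.85 without knockout replicate 1. 10 of 13 glycolytic enzyme genes were higher (median 0.30, camera, adjusted p = 0.0206; adjusted p = 0.589 with an estimated correlation), with Eno1 at 1.06 ± 0.23 and Pgam1 at 1.00 ± 0.26. The glycolysis call was lost without knockout replicate 3 (adjusted p = 0.0727), and under median scaling the median was −0.41, 0.30 above that of all genes. 16 of 24 respiratory chain genes were higher (median 0.17, camera, adjusted p = 0.0464; adjusted p = 0.752 with an estimated correlation), with Cycs, which encodes cytochrome c, at 0.97 ± 0.25 and Cox6c at −0.87 ± 0.29. Its median was −0.57 under median scaling, 0.13 above that of all genes, and the call was lost without control replicate 2 (median 0.07, adjusted p = 0.336), without knockout replicate 1 (adjusted p = 0.109) and without knockout replicate 3 (adjusted p = 0.0998). In these 4 lists 0 members passed over the list alone or over all genes.

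**Figure D3:**
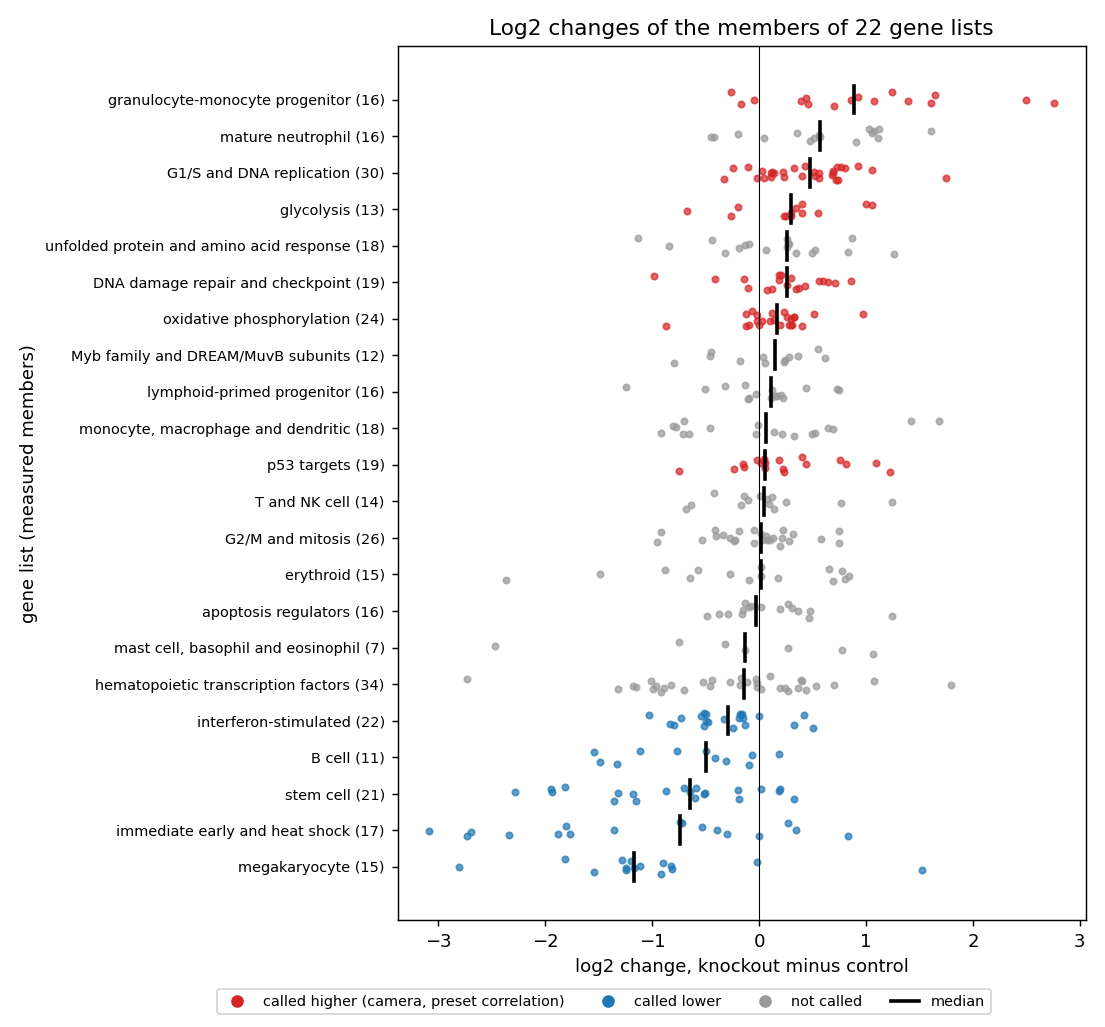
Log2 change from control to knockout (horizontal axis) of every measured member of 22 gene lists, with black bars at the medians and colours for lists called higher or lower by camera with a preset correlation. Medians run from −1.17 for megakaryocyte genes to 0.89 for granulocyte-monocyte progenitor genes, no call held with an estimated correlation, and under median scaling 5 of the 6 lists called higher had medians below 0 (all genes at −0.70).

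The remaining lists were not called, and some held members that moved in opposite directions. Among 34 hematopoietic transcription factor genes (adjusted p = 0.315, median −0.14), 2 were higher and 7 lower adjusted over the list alone, and 0 over all genes. Id1, an inhibitor of differentiation, was at 1.79 ± 0.21 and Egr1 at −2.73 ± 0.89, and the list was called lower without control replicate 1 (median −0.33, adjusted p = 0.0404), while the median was −0.34 without knockout replicate 1, −0.01 without control replicate 2 and 0.02 without knockout replicate 3. Among 15 erythroid genes (adjusted p = 0.513, direction lower, median 0.01, mean −0.16), Car1 (−2.36 ± 0.25), Aqp1 (−1.49 ± 0.23) and Blvrb (−0.88 ± 0.23) were lower and Tfrc, the transferrin receptor gene (0.77 ± 0.21), higher adjusted over the list alone, and 0 passed over all genes. Without knockout replicate 3 that list was called lower (median −0.30, adjusted p = 0.0335), and the median was −0.25 without control replicate 2, 0.06 without control replicate 1 and 0.00 without knockout replicate 1. The hemoglobin gene Hba-a1 was at 11.90 on knockout replicate 3 and between 9.42 and 10.18 on the other arrays. In the unfolded protein and amino acid response (18 genes, adjusted p = 0.315, median 0.26, and −0.65 under median scaling) 3 genes were higher and 2 lower adjusted over the list alone, with Sdf2l1 at 1.26 ± 0.29 and Dnajb9 at −1.13 ± 0.20, and 0 passed over all genes. Its median was 0.00 without knockout replicate 1, 0.05 without control replicate 2 and 0.12 without control replicate 1. Of 18 monocyte, macrophage and dendritic genes (adjusted p = 0.678, median 0.06), F13a1 (1.68 ± 0.27) and the chemokine receptor gene Ccr2 (1.42 ± 0.19) were higher over the list alone and 0 passed over all genes. The median there was −0.14 without knockout replicate 1, 0.01 without control replicate 2, 0.22 without knockout replicate 3 and 0.29 without control replicate 1. Of 7 mast cell, basophil and eosinophil genes (adjusted p = 0.803, median −0.14), Hdc, the gene of histidine decarboxylase (1.06 ± 0.25), was higher and Prss34 (−2.47 ± 0.44) and Cpa3 (−0.75 ± 0.21) lower over the list alone, and 0 passed over all genes. The median turned to 0.70 without knockout replicate 1 and 0.05 without control replicate 1, and was −0.32 without control replicate 2. No member passed either way among 16 genes of lymphoid-primed progenitors (adjusted p = 0.513, median 0.11), with Ighm at −1.24 ± 0.57 and Notch1 at 0.75 ± 0.26, and the median was −0.10 without knockout replicate 1, 0.07 without control replicate 2 and 0.28 without knockout replicate 3. The same held for 14 T and NK cell genes (adjusted p = 0.737, median 0.04), with Nkg7 at 1.24 ± 0.28 and Cd6 at 0.77 ± 0.29, but median scaling called that list higher relative to other genes (adjusted p = 0.0187, median −0.17, 0.54 above that of all genes). With quantile normalization its median was −0.15 without knockout replicate 1, −0.05 without control replicate 2, 0.06 without control replicate 1 and 0.12 without knockout replicate 3. With the stricter detection filter the medians of T and NK cell genes (−0.42), of monocyte, macrophage and dendritic genes (−0.19) and of lymphoid-primed genes (−0.01) turned negative, and none of the 3 was called. Stroma and endothelium, with 4 of 17 genes measured, and sex-linked genes, with 3 of 8, were not tested.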

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

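No setting or test in this part was chosen after the results were seen. Camera called the megakaryocyte, stem cell, granulocyte-monocyte progenitor and G1/S lists in the same direction relative to other genes under every normalization and filter and without each array (adjusted p without an array 2.02e-08 to 2.31e-06, 3.55e-07 to 0.00134, 1.01e-07 to 2.31e-06 and 2.67e-08 to 0.0190). With an estimated correlation 0 lists passed, with adjusted p of 0.589 (megakaryocyte, stem cell, granulocyte-monocyte, interferon, glycolysis) or 0.752 (the other 6 called lists), and with fry 0 passed, with adjusted p of 0.181 (megakaryocyte, granulocyte-monocyte), 0.219 (stem cell, interferon, glycolysis), 0.565 (G1/S, p53, oxidative phosphorylation) or 0.610 (DNA repair, immediate early, B cell). The stricter detection filter, which tests 6140 genes and leaves out those lost in a genotype, called 5 lists and 14 genes (1125 at an unadjusted p under 0.05), and ended the calls of DNA repair (0.378), p53 (0.0566), interferon (0.124), glycolysis (0.124) and oxidative phosphorylation (0.367). Under it Mybl2 was left out and the B cell and mast cell lists had too few members to test. Median scaling called 940 genes (4388 unadjusted) and ended the calls of DNA repair (0.403), B cell (0.594), glycolysis (0.179) and oxidative phosphorylation (0.385), the last of which cyclic loess also ended (0.134). Both settings called mature neutrophil genes higher (loess 0.0239, median scaling 8.09e-09), and median scaling also T and NK cell genes (0.0187). Cyclic loess called 3 genes and trend and robust eBayes 15. In the main fit 418 genes were at least 2-fold apart without overlap. That count was 83 without background correction, 233 with the stricter filter, 347 with cyclic loess and 3124 with median scaling. Unadjusted counts were 3283 without a detection filter, where more genes are tested and the p53 call ended (0.0737), and 3329 in the deposited value table. Without each array in turn 0 genes passed the adjusted threshold, 933 to 1699 had an unadjusted p under 0.05, and adjusted p ran over 1.04e-06 to 0.251 for immediate early genes, 0.00786 to 0.160 for interferon, 0.0178 to 0.0727 for glycolysis, 0.00299 to 0.251 for DNA repair, 0.000171 to 0.227 for B cell, 0.00592 to 0.382 for p53 and 0.0161 to 0.336 for oxidative phosphorylation. The Mybl2 change ran from −0.52 to 0.15 and turned positive without control replicate 1. G2/M genes turned to higher without control replicate 1 (0.0364; range 0.0140 to 0.699) and mature neutrophil genes to lower without knockout replicate 1 (0.00464; range 5.69e-15 to 0.572). The cause was not tested where none is given. Among 258 alternative fits of the 24 named genes 41 passed the adjusted threshold. Their signs could not change without an array, since the genes were chosen for values that do not overlap. The value table was not run for Mybl2 or the lists, since it names no genes, and quantile normalization without background correction, the setting nearest to it, gave −0.11 for Mybl2. No paired analysis was possible because control and knockout share only 1 replicate number. The knockout arrays had fewer genes above background, 10761 and 8797 against 12297 and 13439, which limits statements on dim genes.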

Other observations

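The tests of other splits of the arrays, of mature neutrophil genes (also by scaling), of control replicate 2 and of megakaryocyte against stem cell genes without each array were chosen only after their results were seen, while those of random lists and of megakaryocyte against stem cell genes on all arrays were written before.

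13 genes passed the adjusted threshold both with the stricter detection filter and with trend and robust eBayes, 4 of them higher and 9 lower in the knockout. Besides genes named by rule they included Ndn and 3 further lower genes, chosen here after their values were seen. These were Mmrn1, which encodes the platelet protein multimerin (−2.05), Cavin2, a gene of a caveolar coat protein (−1.90), and Bgn, which encodes the proteoglycan biglycan (−1.96). With the stricter filter their adjusted p in limma was 0.0223, 0.0222 and 0.0222. With trend and robust eBayes it was 0.0357 for each, and in the quantile-normalized fit without either setting no gene passed. 12 of the 13 also passed under median scaling, which called 6 genes higher and 934 lower with all genes at −0.70. With cyclic loess 2 of the 13 passed, Trem3 and MRGPRA2, and none of the 9 lower genes did.

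Xist and Ddx3y differed more between the control arrays than between the knockout arrays. Xist, the RNA of the inactive X chromosome, was at a log2 of 9.16 and 10.29 in the controls and 9.36 and 9.03 in the knockouts. The Y-linked gene Ddx3y was at 7.32 on control replicate 2 and at 5.18, 5.05 and 5.23 on the other arrays. Its detection p was under 0.05 only on control replicate 2 and knockout replicate 3. Eif2s3y, Kdm5d and Uty were not above background on any array. The labels do not give the sex of the pooled mice.

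A split of the 4 arrays by genotype gave 1769 genes with an unadjusted p under 0.05, and the highest of the other splits gave 345. As large a count came from 1 of the 3 splits, the real split, and 3 splits are too few for a share under 0.05.

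Granulocyte-monocyte progenitor genes were higher on both knockout arrays, and 3 explanations were set against each other. Weaker signal on the knockout arrays was tested only as a shift shared by genes of the same mean level. Random lists matched on that level, 10000 in number, had a median change of 0.02, so genes of that level did not share such a shift. Their central 95% range ended at 0.23, below the list's 0.89. The random genes were drawn 1 by 1, so an array effect on correlated genes cannot be told apart this way. The mature neutrophil list, opposite on the 2 knockout arrays, also lay past its range (0.57 against 0.22). So did the unfolded protein list, which was not called (0.26 against 0.23). Medians of p53 targets (0.06, range −0.26 to 0.19) and of oxidative phosphorylation genes (0.17, range −0.16 to 0.20) lay inside their ranges. Camera had called both of these lists, and the other called lists all lay past their ranges. For the progenitor list the camera call was far stronger (adjusted p = 7.10e-08), so a place past the range was close to given. It does not decide whether weaker signal played a part. Mature neutrophils that passed the lineage-negative gate are argued against on knockout replicate 3, where the median of neutrophil genes was −1.01 relative to the control mean and 14 of 16 lay below both controls, S100a8 at 8.69 among them; relative to all genes the median was −0.39 without background correction, −0.50 with cyclic loess and −0.57 with median scaling, near the lower control (−0.35, −0.65 and −0.56) and not raised in any of them. On knockout replicate 1 that median was 2.44 with 16 of 16 above both controls, so there neutrophil RNA cannot be told apart from a change in the progenitors. A change in LSK cells that lost B-Myb, or in the mix of cells within the gate, may underlie the pattern on knockout replicate 3 and stays an untested hypothesis.

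Megakaryocyte genes were lower in the knockout, as were stem cell genes, and random genes of the same mean level did not share either shift. The central 95% range of random lists ended at −0.29 for the megakaryocyte list and at −0.21 for the stem cell list, against medians of −1.17 and −0.65. Those random genes were drawn 1 by 1, so an array effect on correlated genes cannot be told apart this way. Camera had already called both lists against other genes, so this comparison does not decide whether weaker signal played a part. The medians of 14 genes of the megakaryocyte list alone (−1.14) and 20 of the stem cell list alone (−0.63) differed by −0.52 ± 0.22 (SE over genes, which are not independent), past the bound of 2 SE set before, but that bound ignored the spread between arrays. The difference was 0.06 ± 0.23 without knockout replicate 3 and −0.74 ± 0.30 without knockout replicate 1, and without control replicates 1 and 2 it was −0.21 ± 0.28 and −0.42 ± 0.26. A lower share of stem cells in the gate that moves both lists alike therefore cannot be told apart from a loss of megakaryocyte-primed cells after deletion of B-Myb, and either may be a candidate explanation.

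Immediate early and heat shock genes, tested as 1 list, were lower in the knockout, and handling of control replicate 2 is a candidate explanation. Without that array the median change was −0.32 in place of −0.74 and the call was lost, yet the change did not vanish. Handling and genotype therefore cannot be told apart with a single remaining control array. An effect of B-Myb loss on these genes stays open and untested.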
